A study of Mus musculus with 96 samples.

How the data were processed

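The data are a table of cycle thresholds (Ct, the PCR cycle at which product is detected, so that a lower value means more template) for 96 assays in 96 single cells of the uterus of mice at postnatal day 7. Per the labels' protocols, the uterus was digested with type I collagenase, CD326-positive cells were sorted by flow cytometry 1 to a well, and each cell was lysed and preamplified with a 1-step reverse transcription PCR kit. Quantitative PCR with the DNA dye EvaGreen followed on a 96 by 96 Fluidigm Biomark chip, also per the labels. Baseline and threshold settings, quality filters, primer sequences and the number of animals are not given in the sources used here.

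The deposited Ct table holds raw values per the file headers, with no normalization. In it 4320 of 9216 values (46.9%) are exactly 40, which stands for no Ct, and the recorded values run from 9.43 to 29.0. The authors also deposited a ratio table of fold changes, which per the file headers are relative to Gapdh in the same cell and then to cell 1. Recomputing 2 to the power of minus delta-delta-Ct from the Ct table, with undetected values at 40, gave those folds to within 6.55e-06 on the log2 scale. Every column of both tables was matched to a cell by its number, and cells are named by that number.

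Assays carry short names, and gene symbols were taken for 76 of 96 from the names or synonyms of a RefSeq table of mouse genes (assembly GRCm38.p6), used for names only. A further 7 were named through their CD designation, such as CD324 for Cdh1 and CD249 for Enpep, and 5 through the name of their protein, such as the cytokeratin Krt8. For 5 assays the short name fits more than 1 gene: among them, er, pr and p63 were read as Esr1, Pgr and Trp63, and sma was placed with smooth muscle actin on the stromal list under its own name. The assays actin, h2b and cd327 keep their names in the file, and actin was used as a reference gene. Primers were not checked, so an assay that amplifies a related gene, a pseudogene or genomic DNA cannot be excluded. No genome coordinates were used. The values of 1 assay are not reported here.

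A gene was called detected in a cell when its Ct was below 28. The rule was to use the Ct at which the fold-change table reaches its floor, and otherwise 28. Its only floor was the fill value of 40, so 28 applied, and 45 recorded values of 28 or above counted as undetected. The log2 level was 28 minus Ct, on the assumption that each cycle doubles the product, and 0 where undetected. Levels of different genes are comparable only in rough order. The cell filter, at least 1 of Gapdh, actin and Hprt detected, kept all 96 cells. No pair of cells shared an identical recorded Ct in any assay, and the highest correlation of levels between cells was 0.896. Depth per cell is the number of detected genes. A share over 96 cells has an exact 95% interval of about 10 percentage points on either side at 50%, and a gene found in no cell has an upper limit of 3 in 96.

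Lists of marker and pathway genes, the detection rule, the tests, the alternatives and the rule for the genes to name were fixed before the data were examined. Of 21 lists, 5 (ciliated epithelium, Notch, Hedgehog, TGF-beta and BMP, and cell cycle inhibitors) had no measured member. The named genes were Epcam and the reference genes, the 10 genes with the highest share, the 10 nearest 50% of cells, the 5 lowest above 0 and any at 0, up to 4 members with the highest and 1 with the lowest share in each list, and the 10 with the largest SD of level among genes found in at least 50% of cells. To these were added the 10 pairs with the largest excess and the 5 with the largest deficit of co-detection, in SDs of the shuffles. Genes outside this rule, among them Hoxa10, Prom1, Fzd9, Fzd10, Lgr6, Pou5f1, Thy1, Mcam, Cd44 and Itgb3, were chosen after their values were seen.

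Co-detection was counted for genes found in 10% to 90% of cells and set against 1000 seeded shuffles by the curveball method, which keep the total of each gene and each cell. For Eng, pairs with Vim, Krt8, Krt18, Krt19 and Cd24a, which lie outside that band, were also counted in the same way, a step chosen after the data were seen. Association of levels is the Spearman rho of residuals from a linear fit on the number of genes detected, for genes in at least 10% of cells. Clusters came from Ward linkage on Euclidean distances of levels of genes in at least 5% of cells, with 2 to 8 clusters tried, the highest mean silhouette taken, 100 subsamples and 100 shuffled matrices. No p-value was computed, since cells of 1 group are not replicates. No cells were removed as doublets, and leaving out the 10% of cells with the most genes was tried. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

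The co-detection and clustering steps were tested on simulated data of 96 genes in 96 cells. Without structure, 1.57% of pairs fell above and 2.00% below the shuffle range. With planted structure, 60.0% of 15 co-detected pairs and 80.6% of 36 exclusive pairs were found, and 2.89% of other pairs fell outside the range. A pair within the range is therefore not shown to be unrelated. The 2 planted clusters were recovered with an adjusted Rand index of 1. They were simulated without undetected values or differences in depth between cells, so this does not show how clustering performs on the real cells.

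The alternatives were Ct limits of 24 and 26 and any recorded Ct (levels then from 29), cells with all reference genes or with Epcam, cells without the 10% with the fewest or the most detected genes, the deposited fold table, expected numbers from gene totals alone, and other settings for association and clusters. Chosen after seeing the data were the runs without the 8 low-Gapdh cells, without cell 67, without Pecam1 and sma, with levels minus Gapdh and actin in the 95 cells that detect both, and with pairs of genes found in at least 50% of cells. The deposited folds were not used for levels because cell 1, their calibrator, had 81 of 96 assays at 40.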

Results

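Single cells were taken from the uterus of mice at postnatal day 7, when the uterine epithelium is still immature and glands are only starting to form. The organ was digested with collagenase, and cells that bound an antibody to CD326 (EpCAM, an epithelial adhesion molecule) were sorted singly into a plate. After reverse transcription and preamplification, 96 assays were run on each of 96 cells by quantitative PCR in a microfluidic array. The labels give 1 group, with no treatment, control or animal, so the question that could be asked was which genes these cells carry, in what share of cells, and which genes are found in the same cells. Cells of 1 group are not replicates, and no test between groups was possible. Exact (Clopper-Pearson) 95% intervals are given with shares, and they cover counting error only.

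Gapdh, actin and the keratin genes Krt18 and Krt19 were found in nearly every cell, while most patterning and gland genes were found in a minority. Of 9216 values, 4851 (52.6%) had a cycle threshold (Ct) below 28 and counted as detected. A cell detected a median of 54 of the 96 genes, with a mean of 50.5 ± 14.3 (SD, n = 96 cells) and a range of 9 to 78. Of the 96 assays, 10 were detected in at least 90% of cells, 53 in at least 50% and 10 in under 10%. Of those found in any cell, 87 were detected more often in the 50% of cells with the lowest Gapdh Ct, 6 less often and 2 equally often. The median difference was 18.75 percentage points, so an intermediate share is not shown to be the share of cells that carry the gene. Gapdh, a glycolytic enzyme gene, and actin were each detected in 95 cells, and Hprt, a purine salvage gene, in 64. In 8 cells Gapdh came later than a Ct of 18 or was not detected, against a median Ct of 13.4 over all cells. Those 8 low-Gapdh cells detected 9 to 30 genes, and the other 88 cells detected 22 to 78. Cell 67 is 1 of the 8 only because it has no value in any of the first 71 assays in the table, Gapdh among them. Of the last 25 assays it detected 16, against 1 to 6 in the other 7 and a median of 14 in the 88.

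**Figure D1:**
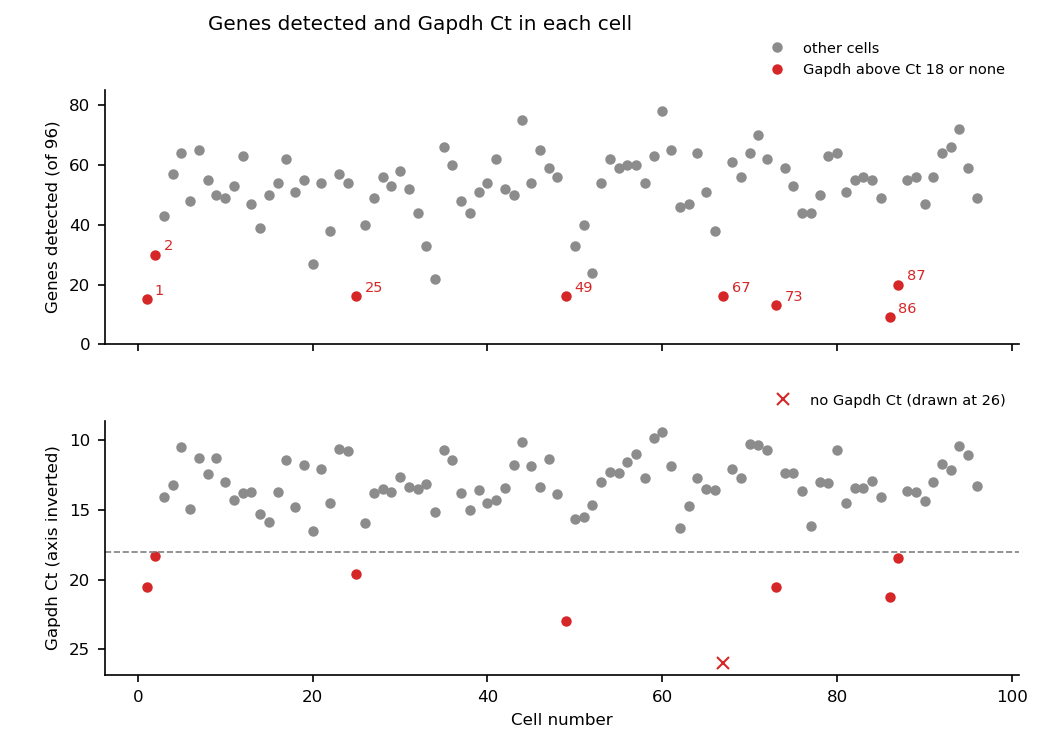
Genes detected (upper panel, of 96 assays) and Gapdh Ct (lower panel, cycles, inverted so that more template is higher) for each cell by its number, with the 8 low-Gapdh cells in red and the dashed line at a Ct of 18. The 8 red cells detect 9 to 30 genes, and cell 67, which has no Gapdh Ct, is drawn as a cross.

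Of the 10 assays found in at least 90% of cells, 4 were on the epithelial list. Krt19 was detected in 96.9% of cells (93 of 96, interval 91.1 to 99.4%), Krt18 in 94.8% (91 of 96, interval 88.3 to 98.3%) and Krt8 in 90.6% (87 of 96, interval 82.9 to 95.6%), all 3 encoding keratins of simple epithelium. Cd24a, a surface glycoprotein gene, was also detected in 87 cells, and Cdh1, which encodes the adherens junction protein E-cadherin, in 85. Epcam, the gene of the antigen used for sorting, was detected in fewer cells, 77.1% (74 of 96, interval 67.4 to 85.0%). These 6 members of the epithelial list were all found in at least 50% of cells. In the cells that detected them, mean levels on a log2 scale (28 minus Ct) were 12.12 ± 3.19 (SD) for Krt18, 12.01 ± 2.52 for Cd24a, 9.53 ± 2.22 for Krt8 and 7.25 ± 2.55 for Epcam.

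Genes that pattern the female tract, which arises from the Müllerian duct, were detected in part of the cells. Wnt7a, a WNT ligand of the uterine epithelium, was found in 54.2% (52 of 96, interval 43.7 to 64.4%), the homeobox and paired-box genes Pax2 in 44.8% (43 of 96) and Emx2 in 41.7% (40 of 96). Among the Hox genes, Hoxa13 was detected in 36 cells, Hoxa11 in 29 and Hoxa10 in 11, and Lhx1, a homeobox gene needed for duct formation, in 6. Only 1 of the 7 measured members of this list, Wnt7a, reached 50% of all cells. In the cells with all reference genes Pax2 reached 63.5% and Emx2 55.6%, and in the cells with Epcam they were at 58.1% and 48.6%. With a Ct limit of 24 the share of Pax2 was 27.1% and that of Lhx1 was 1.04%. Shares also depended on Gapdh. In the 50% of cells with the lowest Gapdh Ct, Wnt7a was at 70.8%, Pax2 at 62.5% and Emx2 at 64.6%. In the other cells they were at 37.5%, 27.1% and 18.8%.

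Of the gland list, Foxa2, a transcription factor gene of uterine glands, was detected in 7.29% of cells (7 of 96, interval 2.98 to 14.4%), Aldh1a1 in 14.6% (14 of 96), Sox9 in 39.6% (38 of 96) and Cdh1, which luminal cells also carry, in 88.5%. Wnt7a, at 54.2%, is also on the list of luminal genes. Trp63, a regulator of basal and squamous epithelium, was detected in 6 cells (6.25%, interval 2.33 to 13.1%), whereas Krt15, a keratin of basal layers, was detected in 56 (58.3%, interval 47.8 to 68.3%). With a Ct limit of 24 the share of Sox9 was 24.0% and that of Foxa2 4.17%, and in the cells with all reference genes that of Foxa2 was 1.59%.

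Both measured steroid receptors were found in most cells. Esr1, the estrogen receptor alpha gene, was detected in 77.1% (74 of 96, interval 67.4 to 85.0%) and Pgr, the progesterone receptor gene, in 57.3% (55 of 96, interval 46.8 to 67.3%). Their levels differed in rough order, with means of 8.21 ± 2.02 and 3.64 ± 2.33 in the detecting cells. Both genes were found together in 50 cells, and 46.3 were expected from shuffles that kept the totals of each gene and each cell (central 95% range 42 to 50). Mki67, a gene of cycling cells, was detected in 30.2% (29 of 96, interval 21.3 to 40.4%) at a mean level of 2.71 ± 2.35. Pgr and Mki67 lay close to the limit: with a Ct limit of 24 their shares were 22.9% and 8.33%.

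All 4 measured members of the growth factor list reached 50% of cells: Igf1r, the receptor of insulin-like growth factor 1, in 91 cells, Kit, the stem cell factor receptor, in 81, Igf2r in 73 and Insr in 56. Kit was detected at a low mean level of 4.46 ± 1.94, and with a Ct limit of 24 its share was 53.1% in place of 84.4% and that of Insr was 49.0% in place of 58.3%. Of 11 WNT genes, 7 reached 50% of cells, among them the receptor Fzd7 in 87 cells (90.6%, and 78.1% with a Ct limit of 24), Ctnnb1 (beta-catenin) and Myc in 85 each (88.5% with either limit) and the R-spondin receptor Lgr4 in 78. Its relatives Lgr6 and Lgr5 were detected in 57 and 20 cells, Wnt5a in 40, Fzd4 in 54, Fzd9 in 30 and Fzd10 in 29.

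Of 33 genes on the stem and progenitor list, 17 were found in at least 50% of cells. Bmi1, a Polycomb gene, was detected in 93 cells, Cd24a in 87, and Klf4 and Myc in 85 each. Over the detecting cells outside the low-Gapdh group, the Ct of Bmi1 and Klf4 followed that of Gapdh at a rho of 0.34 and 0.14. The median over genes was 0.51. Cd44 and Cd9 were each detected in 77 cells, Itga6, an integrin of the basal cell surface, in 68, and Prom1 (CD133) in 38. Of the 8 pluripotency genes, 3 reached 50%: Klf4, Nanog (77 cells, 80.2%, interval 70.8 to 87.6%) and Sall4 (57 cells). Pou5f1, which encodes OCT4, was detected in 7 cells, Esrrb in 3 and Lin28a in 0 of 96, which allows a share of up to 3.12% by the limit of 3 counts and 3.77% by the exact interval. With a Ct limit of 26 the share of Sall4 was 46.9%.

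**Figure D2:**
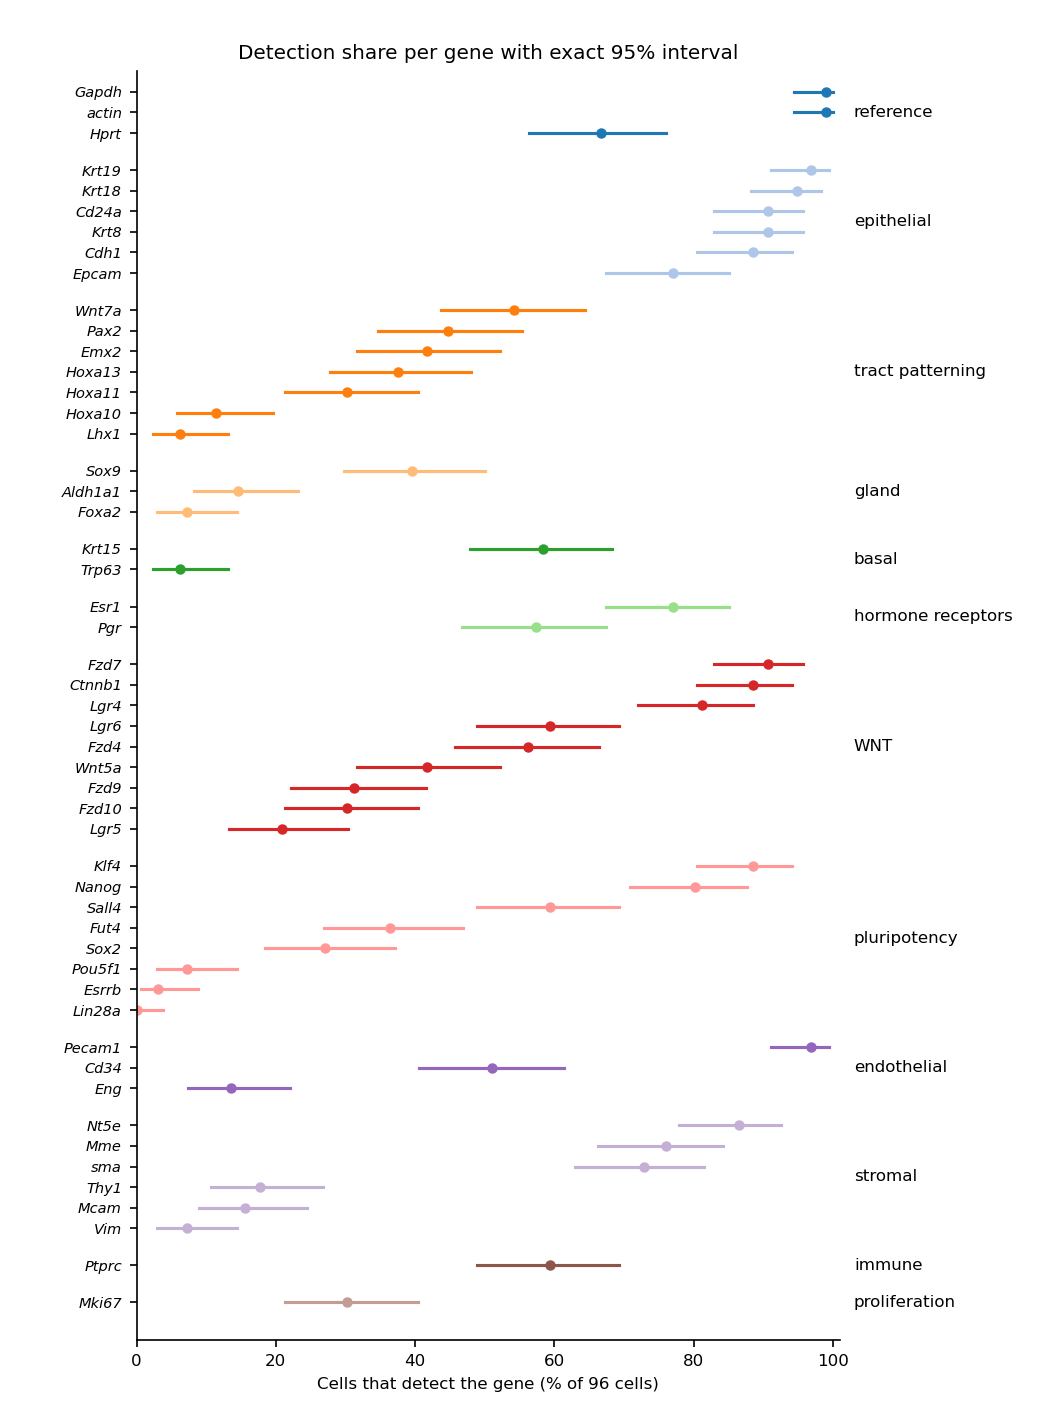
Share of the 96 cells that detect each gene (points, horizontal axis in percent) with its exact 95% interval (lines), for genes grouped by list. Keratins Krt19, Krt18 and Krt8 lie above 90% of cells, and Foxa2, Trp63, Vim and Pou5f1 lie under 10%.

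Markers that the lists assign to other cell types were found in most cells too. Of 12 such markers, at least 1 was detected in 94 cells (97.9%, interval 92.7 to 99.7%) and at least 2 in 91 cells (94.8%, interval 88.3 to 98.3%). Without Pecam1 and sma, a run chosen after the data were seen, these shares were 92.7% and 89.6%. The median cell detected 6 of the 12 markers, while 52.6% of the values of the whole panel were detected. The high shares therefore do not set these markers apart from the other assays. The markers were uneven within each type. Pecam1, an endothelial adhesion gene, was detected in 93 cells, Cd34 in 49 and Eng, an endothelial and stromal co-receptor gene, in 13 (13.5%, interval 7.41 to 22.0%). On the stromal list, Nt5e was detected in 83 cells, Mme in 73 and sma in 70, whereas Thy1 was detected in 17, Mcam in 15 and Vim, the mesenchymal intermediate filament gene, in 7. The only immune marker, Ptprc (CD45, a leukocyte phosphatase), was detected in 57 cells (59.4%, interval 48.9 to 69.3%). The only mesothelial marker measured was Krt19, which is also on the epithelial list. The Ct of Pecam1 did not follow that of Gapdh over the 88 cells outside the low-Gapdh group (Spearman rho = -0.01, Pearson r = -0.17, and r = -0.20 without the 2 cells farthest from the median), whereas that of Ptprc did (rho = 0.75, r = 0.77 and 0.73 in 57 cells). No p is given, because cells of 1 group are not independent.

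**Figure D3:**
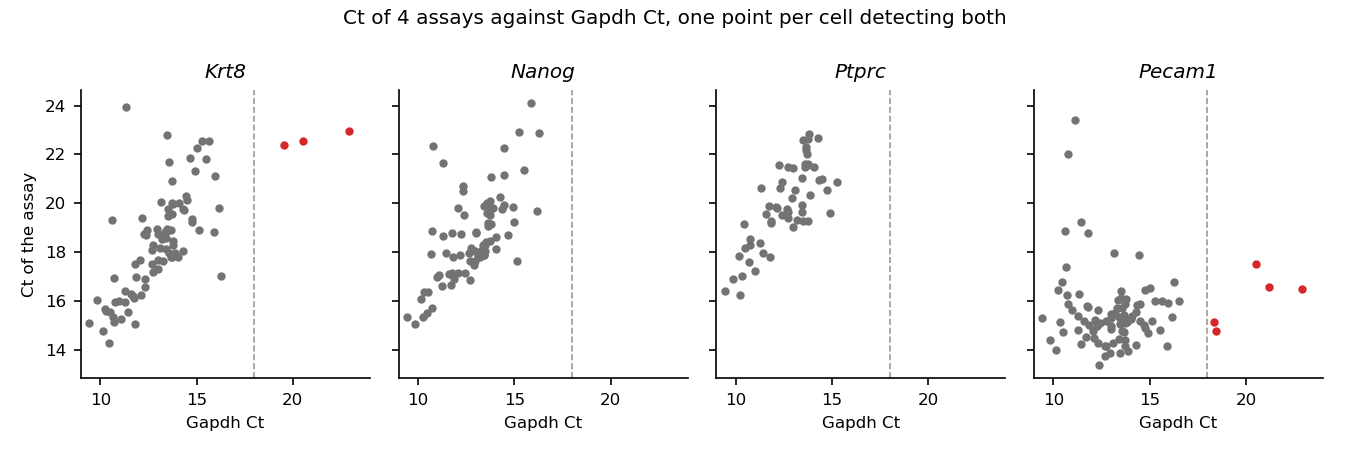
Ct of Krt8, Nanog, Ptprc and Pecam1 (vertical axes, cycles) against the Gapdh Ct of the same cell, one point per cell that detects both, with low-Gapdh cells in red and the dashed line at a Ct of 18. Krt8 (rho = 0.74), Nanog (rho = 0.66) and Ptprc (rho = 0.75) rise with Gapdh Ct, and Pecam1 does not (rho = -0.01).

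Cd55, Epcam, Cd9, Wnt7a and Pax2 formed several of the pairs found together more often than in shuffles keeping gene and cell totals. Over 2850 pairs of 76 genes, 162 pairs were detected together more often than the central 95% range of the shuffles and 144 less often, where the shuffled data themselves gave means of 30.0 and 37.3 and maxima of 54 and 66. Cd55, a complement regulator gene, and Wnt7a were both found in 48 cells against 37.3 expected (range 33 to 42), Cd55 and Epcam in 60 against 51.1, and Cd55 and the tetraspanin gene Cd9 in 60 against 52.8. Wnt7a was also found with Pax2 in 37 cells against 27.0 expected, with Hprt in 49 against 38.7, with Hopx in 32 against 22.8 and with Itga6 in 49 against 41.0. Enpep, an aminopeptidase gene, and Ptprc were both found in 51 cells against 41.2 expected, Cd164 and Itgb1 in 81 against 75.1, and Cd164 and the prion protein gene Prnp in 83 against 77.6.

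Eng was found with Cd9, Epcam and Cd55 in fewer cells than expected. Of its 13 cells, 4 detected Cd9 against 11.6 expected (range 9 to 13), 4 detected Epcam against 11.3 (range 9 to 13) and 2 detected Cd55 against 9.76 (range 7 to 13). Tbx3, a T-box transcription factor gene, was found with Cdh1 in 15 cells against 20.8 expected (range 19 to 22), and Aldh1a1 with Kit in 8 against 12.9 (range 11 to 14). Among the 74 cells that detected Epcam, Eng, Cd9 and Cdh1 fell outside the 10% to 90% band of detection, so their pairs could not be counted.

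**Figure D4:**
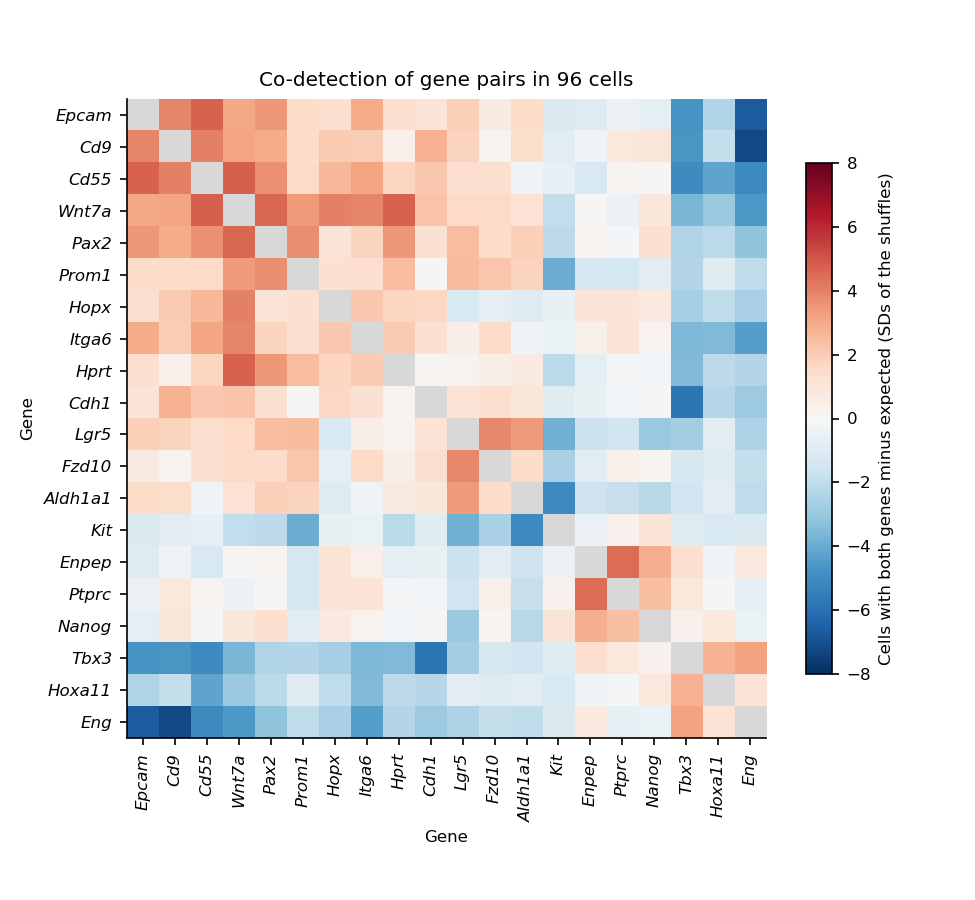
Cells that detect both genes of a pair minus the number expected, in SDs of the shuffles (colour), for 20 genes on both axes, with grey where no value was computed. Red marks an excess, as for Cd55 with Wnt7a and Enpep with Ptprc, and blue a deficit, as for Eng with Cd9 and Epcam.

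Levels of Cdh1 varied with those of Cd9, Cd24a and Krt18. After a linear fit on the number of genes detected per cell was subtracted, 69 of 3655 pairs of 86 genes had a Spearman rho of at least 0.5, none had -0.5 or below, and the median absolute rho was 0.125. The highest were Cdh1 with Cd9 (rho = 0.73, Pearson r = 0.68), Cd24a with Cdh1 (0.71 and 0.68) and Wnt7a with Hprt (0.68 and 0.66). Cd9 with Krt18 (0.66 and 0.59), Cdh1 with Krt18 (0.66 and 0.62) and Epcam with Wnt7a (0.65 and 0.65) followed. Epithelial genes did not all vary together: Cd24a with Krt8 had a rho of 0.08 and an r of -0.04. Without the subtraction 467 pairs passed, and with Pearson r 45. Rarely detected genes share many undetected cells, whose residuals come from the fit alone, so rho between them can depart from r in either direction. Eng and Itgb3 had a rho of 0.65 but an r of 0.32, and Abcg2 and Itgb3 a rho of -0.44 but an r of -0.04. The cause was not tested. Among the 53 genes found in at least 50% of cells, 45 of 1378 pairs had a rho of at least 0.5, a restriction chosen after the data were seen.

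Clusters of cells differed in the number of detected genes and changed with the settings. Ward clustering of levels over 94 genes gave 2 clusters of 15 and 81 cells, with a mean silhouette of 0.21. It was at most 0.036 when each gene was shuffled across cells. That shuffle also removes the differences in depth between cells, so the contrast does not show clusters beyond depth. The smaller cluster held all 8 low-Gapdh cells, with a median of 22 detected genes against 55 and a median Gapdh Ct of 18.3 against 13.0. Over 100 subsamples of 80% of the cells the adjusted Rand index had a median of 0.53 and ranged from -0.11 to 1. Without cell 67 alone the 2 clusters held 68 and 27 cells, with an adjusted Rand index of -0.09 to those of all cells. With Ct limits of 24 and 26 they held 67 and 29 and 66 and 30 cells, with indices of -0.08 and -0.07. Without the low-Gapdh cells they held 61 and 27 cells with medians of 51 and 62 detected genes, so that no cluster was named as a cell type.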

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

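The tests without the 8 low-Gapdh cells, without cell 67, without Pecam1 and sma, minus Gapdh and actin in 95 cells, and on genes in at least 50% of cells were chosen after the result was seen. Of 131 values of the main results under the alternatives, 98 stayed within the counting interval, 1 SD or 1.5 times their value (0.05 for the silhouette, an equal number for clusters), and 33 moved. The main filter keeps all cells and the main limit is 28, so these settings change nothing. The normalization to reference genes found in all kept cells could not be run, as none was found in all 96. No paired analysis was possible because there is 1 group.

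The median over genes of the mean level, 7.95, was 4.15 with a Ct limit of 24, which follows from the scale, 3.93 with undetected cells at 0, 11.78 on the log2 deposited folds and -7.00 minus Gapdh and actin. Assays in at least 90% of cells rose from 10 to 22 in the 63 cells with Gapdh, actin and Hprt, 20 in the 74 with Epcam, and 19 without either the lowest 10% of cells by detected genes or the low-Gapdh cells. Cells with at least 2 other-type markers were 98.4% with all reference genes and 100% without either the lowest 10% or the low-Gapdh cells, where those with at least 1 were also 100%. Pairs above and below the shuffles numbered 75 and 85 with all reference genes and 67 and 84 with Epcam. These came from fewer cells and from fewer genes in the 10% to 90% band. They do not compare directly with the counts over all cells, and no other cause was tested. Against gene totals alone, which ignore depth, the pairs above and below numbered 1145 and 41. Wnt7a and Itga6 stayed 2.95 cells above the expected number in the cells with Epcam, inside the shuffle range. The other 131 values of the named pairs that could be computed stayed outside it on the same side. For gene totals alone, the width of the shuffle range was set around that expectation. Without the lowest 10% or the low-Gapdh cells, Cd164 with Itgb1, Cd164 with Prnp and Cdh1 with Tbx3 gave no value. A gene of each had left the 10% to 90% band, so their dependence on shallow cells was not checked.

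Level pairs with a rho of at least 0.5 were 121 with all reference genes, 467 without the fit on detected genes, 45 with Pearson r and 45 among genes in at least 50% of cells. Clusters numbered 3 with all reference genes, 3 minus Gapdh and actin and 4 on the deposited folds, in place of 2. The silhouette of 0.21 became 0.136 with all reference genes, 0.146 with Epcam, 0.148 without the lowest 10%, 0.150 without low-Gapdh cells, 0.0941 minus Gapdh and actin, 0.0810 on deposited folds and 0.445 with average linkage, which set 1 cell against 95. Agreement with the 2 clusters of all cells ranged from an adjusted Rand index of -0.09 without cell 67 to 0.83 with scaled genes; the cause was not tested. Of 528 shares of named genes under the alternatives, 84 left their interval.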

Other observations

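All tests in this part were chosen after the result was seen. Integrin subunits differed widely in how many cells detected them. Itgb1, the common beta subunit, was detected in 82 cells, Itga6 in 68, Itga3 in 63, Itga5 in 45, Itgae in 34, Itga2 in 20, Itgb3 in 12 and Itga1 in 8. Among other surface and junction genes, Cd200 was detected in 70 cells, Cd40 in 68, Gja1, the gap junction gene for connexin 43, in 62, Ncam1 in 50, Il17ra in 48, Dpp4 in 30 and Mst1r in 26. Msi1 was detected in 58 cells, Ezh2 in 62, Nes in 23, Abcg2 in 26 and Tert in 12.

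Lgr5 was detected in 20 cells, and all 20 detected Epcam, where the shuffles gave 17.3 (range 14 to 20). Lgr5 and Fzd10 were both found in 15 cells against 7.77 expected from the shuffles (range 4 to 12), and Lgr5 and Aldh1a1 in 9 against 3.92 (range 1 to 7). Prom1 was found with Pax2 in 29 cells against 20.3 expected (range 16 to 25) and with Wnt7a in 32 against 24.1 (range 20 to 28). Hoxa11 and Tbx3 were both found in 14 cells against 8.56 (range 5 to 12).

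The Ct of Pecam1, detected in 93 cells, did not follow that of Gapdh, although low-Gapdh cells 1 and 25 lacked it, as they lacked Bmi1, and in cell 67 it lies in the block of missing assays. A template that does not scale with the RNA of the cell, such as genomic DNA or an unspecific product, may contribute. In the 5 of 7 low-Gapdh cells, cell 67 left out, that detected Pecam1 its mean Ct was 0.53 cycles later than in the other cells. The mean Ct of actin was 4.95 cycles later over all 7, cells 1 and 25 among them, so its shift is not over the same cells. Bmi1 was nearer to Pecam1, at 1.03 cycles later, and its levels varied with those of Pecam1 (rho = 0.62, r = 0.75). Such a template stays open for Pecam1, since its shift is 3.93 cycles when cells 1 and 25 are set at the limit of 28. The CD326 sort selects against single endothelial cells, but these or doublets with them also stay open. Eng was detected in 14.0% of the cells with Pecam1 and Cd34, the other endothelial gene measured, in 52.7%. Since 93 cells detected Pecam1, these shares nearly repeat those over all cells (13.5% and 51.0%) and cannot decide the question. No biological explanation was tested.

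Nanog, Dppa2, Tdgf1, Sall4 and Ptprc, which mark pluripotent, germ or blood cells, were detected in 77, 82, 67, 57 and 57 cells. Their Ct rose with that of Gapdh at a median rho of 0.66 (range 0.46 to 0.75). Of the 7 low-Gapdh cells other than cell 67, 0, 1, 0, 1 and 0 detected them. This argues against a template that does not scale with RNA only if preamplification yield was alike across cells and those 7 wells held a cell. Neither was tested, so that explanation is not excluded. Of the other pluripotency genes, Klf4 was detected in 85 cells, Fut4 in 35, Sox2 in 26, Pou5f1 in 7, Esrrb in 3 and Lin28a in 0. Doublets with cells that carry Pou5f1, Esrrb or Lin28a could give only a small part of the 77 cells with Nanog, unless those assays missed them. Doublets with other cells stay open. Amplification of a related transcript by these assays stays open, because primers were not examined, and so does a shared dependence of all assays on preamplification yield. No biological explanation was tested.

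Eng went with absence of Epcam, Cd9 and Cd55, and so did Tbx3, found with Epcam in 12 cells against 18.9 expected (range 16 to 21), with Cd9 in 13 against 19.4 (range 17 to 22) and with Cd55 in 7 against 16.2 (range 13 to 20). Eng was also found with Cdh1 in 10 cells against 12.3 (range 11 to 13), with Wnt7a in 1 against 8.53 (range 5 to 12) and with Pax2 in 2 against 7.19 (range 4 to 10), while Hoxa11 was found with Cd55 in 13 cells against 21.3 (range 17 to 25), but with Epcam in 21 against 25.0, inside the range of 21 to 28. Eng and Tbx3, which is not on the stromal list, were found together in 9 cells against 3.96 (range 1 to 7). Stromal cells carried through the CD326 sort may contribute, since Eng had a median association of -0.18 with 5 epithelial genes. Eng was also found with Vim in 4 cells against 1.36 expected (range 0 to 3). The stromal explanation stays open: all 13 cells with Eng detected Krt8, Krt18 and Krt19. For these keratins the shuffles gave 12.5, 12.7 and 12.9, because nearly all cells detect them. Of the 13 cells, 11 detected Cd24a against 12.5 (range 11 to 13). Vim, itself in 7.29% of cells, was the only 1 of the 8 other stromal genes on the list found with Eng above the shuffles. The median association of 0.31 with those 8 includes rarely detected genes, whose rho can depart from Pearson r. No biological explanation was tested.

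Cells 1, 25, 49 and 73, which are 24 numbers apart, detected 15, 16, 16 and 13 genes, a mean of 15.0, and the next lowest mean among the 24 sets with this spacing was 34.5. Cell 67 detected 0 of the first 71 assays in the table and 16 of the last 25. In the deposited fold table, 88.0% of values have either cell at a Ct of 40. Its median log2 fold was 12.78 where cell 1 had no Ct and the other cell did, and -2.44 where both had one. The highest fold, 4.61e+12, was in cell 67, which has no Gapdh Ct.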
